A study of Homo sapiens with 6 samples.

How the data were processed

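RNA was measured in HepG2 cells 48 h after transfection with a control siRNA (3 libraries) or an H19 siRNA (3 libraries). Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a strand-specific total RNA kit, and sequenced as paired reads of 76 cycles. Per the submitters' processing notes, the tools were STAR 2.5.0a, Cufflinks 2.2.1 and DESeq2 1.0.0 and the genome build was hg19. The notes give no role or order for these tools, and the gene annotation, the treatment of reads that map to several places and the use of strand in counting were not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate cultures, so the authors' SEs and adjusted p-values can reflect only the spread between these libraries, which may be technical. The p-values of the tests added here were computed across genes, with 1 value per group, and do not measure that spread.

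The authors deposited 1 table for the whole series, used here throughout. Per the file headers it gives, for each gene, the log2 count in siCon and in siH19, a mean count, a log2 fold change, its standard error and a q value, an adjusted p. The group values and the fold change are on a log2 scale, as deposited by the authors. The mean count deposited by the authors is a normalized signal and not a whole number of reads. The q value (an adjusted p-value) deposited by the authors was under 0.05 in every row, with a largest value of 0.0498, so the table holds called genes only. It was written as 0 for 287 genes, which means below the table's precision, and the smallest value above 0 was 1e-06. The authors combined the libraries into 1 value per group, so no value per library was used, and the number of columns from samples outside the series was 0.

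The table was checked against itself. The deposited fold change equalled the difference of the deposited group values within 0.01 in all rows, siH19 minus siCon, and the mean count equalled the mean of the group values within 0.339%. The deposited SE ran from 0.06 to 0.22, with a median of 0.11. For 52 of the 108 genes with a mean count under 50, the deposited SE was smaller than counting error alone would give for 3 libraries per group: 0.21 against 0.342 for the gene with the lowest mean count. The sources used here do not say whether fold changes were shrunken, so sizes for genes with low counts carry that doubt. Since library totals were not given, depth per library is unknown and no counting interval was computed for single genes. An SE, fold change or q printed for a gene is the authors' and was not recomputed.

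The following choices were made before the data were examined: the sample groups, the tests, 32 gene lists with 1015 symbols, most of the alternatives and the rule for named genes. The rule takes H19, the 8 largest rises and 8 largest falls among genes with a mean count at or above the median of the listed genes, the 3 genes of highest mean count, the 2 largest absolute changes in each list with at least 3 listed members, and those of 11 genes fixed by name that the table holds. It gave 73 genes, and some of these, with the result of 1 list, are not reported here. Other genes in the text were chosen after their values were seen, as further examples of their list. The design had foreseen a model fitted to values per library where the file held them. As the file held the authors' comparison, the alternative written for that case was used and no test of single genes was added.

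The share of genes lower in siH19 was tested with a two-sided exact binomial test, with an exact Clopper-Pearson 95% interval. Each list with at least 5 listed members (23 of 32) was tested with a two-sided Fisher's exact test of higher against lower, its members against the other listed genes, with Benjamini-Hochberg adjustment over the 23 lists. With called genes only there is no background of genes that could have been called, so this tests the direction of listed members and not the enrichment of a list, and no count adjusted over the list alone could be made. Of the 1015 symbols 236 were listed. The relation of fold change to mean count used a Spearman correlation with 100000 permutations. Chromosomes with at least 10 listed genes were tested with Fisher's exact test. List medians were compared with 100000 random sets of listed genes in a permutation test.

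Gene positions, transcripts and 3' UTRs came from GENCODE release 29, on a different genome build from the one in the submitters' notes, so no coordinates are printed and it was used for chromosome membership, neighbours, overlaps and sequence. Of the 1998 symbols 1971 (98.6%) were matched, 54 of them by an older symbol, and 1930 were protein coding. 3 names had been turned into dates and were left unmatched. Of the listed genes, 88 overlap another listed gene in 45 pairs, 26 of which moved in 1 direction, including those of BHMT, BHMT2, CYFIP2, CLDN2, TAGLN and LYVE1. Reads of such pairs, and of near-identical paralogs, could be divided wrongly between genes.

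A search added after seeing the data scored 14263 sequences of 7 bases, each in at least 30 genes, in the 3' UTRs of the 1897 listed genes with an annotated 3' UTR of at least 50 bases. For each sequence a z compared the fold changes of genes with and without it, and 1000 shuffles of the fold changes gave the limits of the most extreme z (5th percentile -4.44, 95th percentile 4.47). Families of genes that share a symbol stem were also tested after seeing the data.

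The list test, also used for gene families, and the sequence search were checked on simulated data. In 100 simulated sets of 1998 genes with no effect, the list test called any list in 2%, and it called 79% of planted lists with at least 12 listed genes and 95% of members lower. These sets shuffled the fold changes among genes, so the 2% does not cover lists whose members change together. In 10 simulated sets of 1897 genes a sequence given a shift of -0.3 ranked first in 10, and 1 of 10 sets with no effect passed the lower limit. Alternatives tried were stricter adjusted p thresholds (0.01 and 0.001), minimum changes of 1.5-fold and 2-fold, a minimum level, the removal of unmatched, pseudogene and small RNA rows and, added after seeing the data, the removal of overlapping genes, of genes with either 3' UTR sequence together with those whose 3' UTR was not searched, and of members shared between lists, with some of the other settings also added then for the list, abundance and chromosome results. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.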

Results

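HepG2 is a human liver cancer line that keeps many functions of hepatocytes and is often used as a liver cell model. The cells were transfected with a control siRNA (siCon, 3 libraries) or with an siRNA against H19 (siH19, 3 libraries) and collected after 48 h. H19 is a long noncoding RNA transcribed from an imprinted locus next to IGF2. Total RNA depleted of ribosomal RNA was sequenced from all 6 libraries, and the comparison asks which transcripts depend on H19 in hepatic cells. The authors' deposited table lists 1998 genes called as changed, each with 1 combined value per group, a fold change, its standard error (SE) and an adjusted p. Library totals were not given in the sources used here, so the sequencing depth is unknown. The mean normalized count per listed gene ran from 12.3 to 240657, with a median of 640, and 1779 genes had a mean of at least 100. H19's own level was not analysed here, so the extent of the knockdown was not checked, and siH19 is the submitters' label.

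Genes for secreted liver proteins, complement and coagulation, and cholesterol synthesis were lower in cells that received the H19 siRNA, and extracellular matrix genes were higher, by the list tests given with each group. The calls were unequally stable: the alternatives kept them in 9 of 9 for secreted liver proteins, 7 of 9 for complement, 4 of 7 for cholesterol and 3 of 9 for matrix genes. In the authors' deposited table the largest fall among the named genes was in G6PC, the catalytic subunit of the enzyme that releases free glucose from liver cells, at a log2 fold change of -1.91 ± 0.17 (SE), a 3.76-fold fall. SULT2A1, which sulfates steroids and bile acids, and AKR1B10, an aldo-keto reductase, both changed by -1.53 in the authors' deposited table. The same authors' deposited table gave -1.48 ± 0.07 for TGFBR2, a receptor for TGF-beta, -1.31 ± 0.12 for NR1H4, the nuclear bile acid receptor, and -1.22 ± 0.10 for SLC2A2, the main glucose transporter of hepatocytes. Among well-expressed genes that rose, the authors' deposited table gave 1.20 ± 0.09 for CD24, a surface glycoprotein, and 1.11 for both MCAM, an adhesion molecule, and XPR1, a phosphate exporter. These were followed in the authors' deposited table by YWHAH (1.10), CHPF (1.07), the basement membrane protein NID1 (1.06), the adhesion molecule ALCAM (1.05) and the tubulin TUBA1A (1.03).

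Other large falls at well-expressed genes in the authors' deposited table were those of SMLR1 (-1.27), DAZAP2 (-1.22), the lysosomal glycoprotein CD68 (-1.21) and the chemokine CCL20 (-1.20). The 3 listed genes with the highest mean normalized count were all lower in siH19, with log2 fold changes in the authors' deposited table of -0.70 ± 0.09 for APOB, -0.60 ± 0.08 for SERPINA1 and -0.41 ± 0.08 for the ferritin light chain FTL. In all, the authors' deposited table gave 893 genes as higher and 1105 as lower in siH19. The share that was lower, 55.3% (exact Clopper-Pearson 95% interval 53.1 to 57.5), differed from an even split (two-sided exact binomial test, p = 2.30e-06), with the caution that genes are not independent of each other. Most changes were small: the median log2 fold change was 0.46 among the higher and -0.44 among the lower genes, which is 1.38-fold and 1.36-fold. At least a 2-fold change was listed for 35 higher and 48 lower genes in the authors' deposited table, and in that subset of 83 the split was not distinguishable from even (57.8% lower, exact binomial test, p = 0.187).

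**Figure D1:**
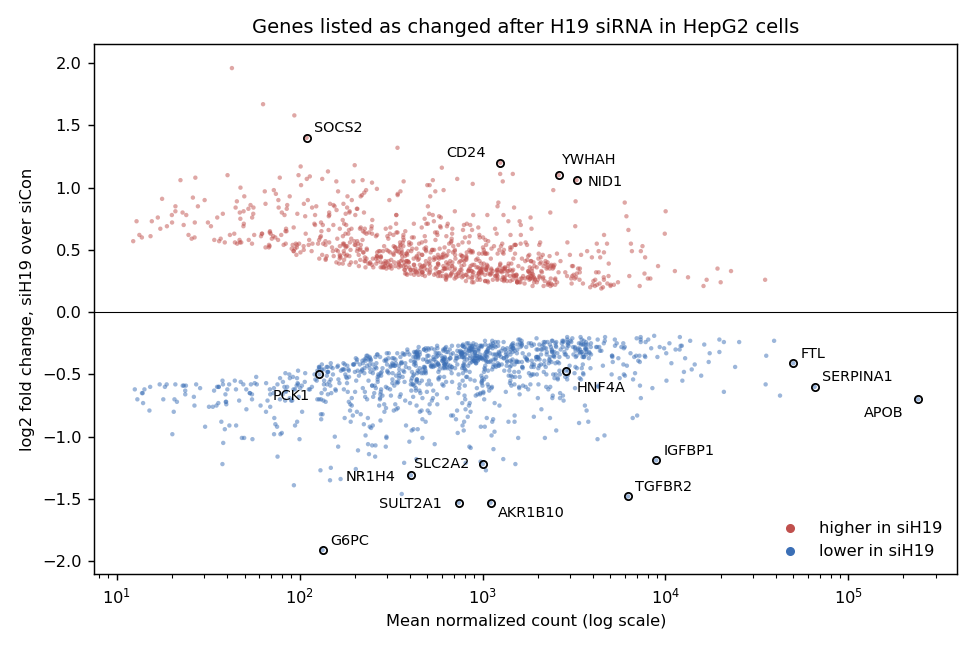
Each point is 1 of the 1998 genes in the authors' deposited table, with its mean normalized count on a log scale (x axis) and its log2 fold change, siH19 over siCon (y axis). Red marks the 893 higher and blue the 1105 lower genes, and circled genes are named, from G6PC at -1.91 to SOCS2 at 1.40, with APOB at the highest mean count (240657).

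Fold changes were tied to short sequences in the 3' untranslated region (UTR), which some of the named genes carry. Of 1897 listed genes whose annotated 3' UTR was searched, 302 held CATCAAA, and 74.2% of these were lower in siH19, against 50.8% of the genes without it. A different sequence, GCAGTAC, was held by 161 genes, of which 16.1% were lower, against 58.1% of the genes without it. Both ties lay beyond those of all 14263 sequences in 1000 shuffles of the fold changes (permutation p = 0.000999 for each, the smallest these can give). Among the named genes, CATCAAA was found in CD24, NID1, TGFBR2, DAZAP2, SLC2A2, C8A, SLC38A4, TOP2A, CDKN1A and LIN28B. GCAGTAC was found in XPR1, YWHAH, CHPF, NID1, ALCAM, DAZAP2, IL1RN and LIN28B. Neither was found in G6PC, SULT2A1, AKR1B10, NR1H4, HNF4A, APOB, SERPINA1 or any of the 29 listed hepatocyte genes, and HIST1H1D, HIST1H1B and RPL12 were not searched. Genes given below as further examples can hold these sequences too, such as FOXO3, DNMT1, COL4A6 and SEMA4F for GCAGTAC and ICAM1 and SLC22A3 for CATCAAA. Overlapping sequences also passed the shuffled limits, ACATCAA on the lower side and CAGTACA and CAGTACT on the higher side, and were not looked up in single genes. This search was chosen after the gene table had been seen.

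Genes for secreted liver proteins and hepatocyte identity fell together. All 29 listed members of this set, out of 50 symbols, were lower in siH19, with a median log2 fold change of -0.63, against 54.6% lower among the other listed genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 7.24e-07 over 23 lists). The list tests treat genes as independent, so their p-values can be too small where members change together. In the authors' deposited table the falls were largest for KNG1, a kininogen (-1.16 ± 0.20), and for APOM (-1.08 ± 0.11), a lipoprotein component, and smallest for ORM2 (-0.22). Albumin (ALB) stood at -0.67 ± 0.07, transthyretin (TTR) at -0.88 ± 0.09 and the fetal liver protein AFP at -0.35 ± 0.07 in the authors' deposited table. The liver transcription factors HNF4A and CEBPA were among the 29, at -0.47 ± 0.09 and -0.69 ± 0.11 in the authors' deposited table. Complement and coagulation genes showed the same direction, with all 18 listed members, out of 38 symbols, lower and a median of -0.50 (Fisher's exact test, adjusted p = 3.79e-04). They were led in the authors' deposited table by antithrombin, SERPINC1 (-1.08 ± 0.12), and the complement component C8A (-0.85 ± 0.15). SERPINC1, FGA, FGB and FGG stand in both lists, and without members shared between lists the adjusted exact p was 5.25e-05 for the hepatocyte and 0.00487 for the complement genes. The complement call was lost among genes with a mean level at or above the median (adjusted exact p = 0.119) and among those changed at least 1.5-fold (0.0819), within a range of 3.65e-04 to 0.119 over 9 alternatives.

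**Figure D2:**
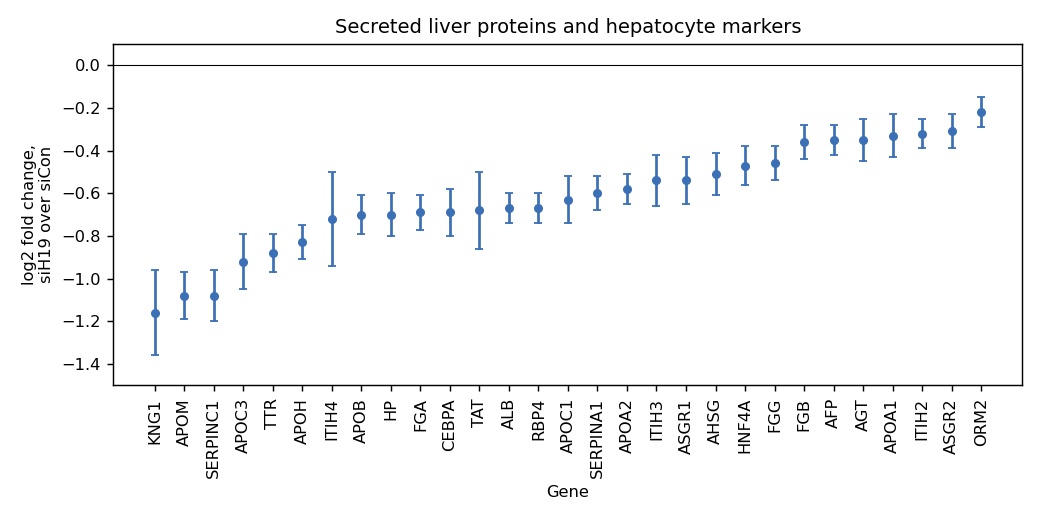
Points are the log2 fold changes (y axis, siH19 over siCon) of the 29 listed secreted liver proteins and hepatocyte markers (x axis) in the authors' deposited table, and bars are 1 SE to each side as given there. All 29 lie below 0, from KNG1 at -1.16 to ORM2 at -0.22.

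Markers of other cell types moved in both directions beside the hepatocyte genes. The cells were a single line, HepG2, so these transcripts do not by themselves show that other cell types were present. Of 5 listed bile duct and progenitor genes, 4 were higher, CD24, SOX4 (0.73 ± 0.12), SPP1 (0.53 ± 0.09) and PROM1 (0.40 ± 0.12), and ONECUT2 was lower (-0.69 ± 0.13) in the authors' deposited table. The list did not pass the direction test (Fisher's exact test, adjusted p = 0.413). A list of 5 could not pass even with all members in 1 direction, so this leaves a difference from the other listed genes open. The few other listed markers were lower in the authors' deposited table: ACTA2 of stellate cells (-0.83), LYVE1 of endothelium (-0.98, a gene that overlaps the listed gene MRVI1, so that reads could be shared), and CD68 (-1.21) and LYZ (-0.64) of blood cells. These last 3 lists had too few listed members for a test.

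Listed cholesterol genes fell modestly. All 10 listed genes of cholesterol synthesis and uptake, out of 27 symbols, were lower in siH19, with a median of -0.39 (Fisher's exact test, adjusted p = 0.0225). In the authors' deposited table they included the transcription factor SREBF2 (-0.38 ± 0.10), which drives genes of the pathway, and the enzymes CYP51A1 (-0.47 ± 0.08) and ACAT2 (-0.45 ± 0.08). The call was lost at an adjusted p threshold of 0.01 (adjusted exact p = 0.195), at mean levels at or above the median (0.207) and in a permutation test of the list's median (0.549), within a range of 0.0157 to 0.549 over 7 alternatives. In fatty acid and triglyceride synthesis 11 of 12 listed genes were lower, and in fatty acid oxidation and ketogenesis also 11 of 12, and neither list passed (Fisher's exact test, adjusted p = 0.0609 for each). Their largest changes in the authors' deposited table were at the lipid droplet protein CIDEC (-0.97 ± 0.19) and the lipoprotein assembly factor MTTP (-0.88 ± 0.09), and at BDH1, a ketone body enzyme (-1.08 ± 0.15), and the fatty acid binding protein FABP1 (-1.02 ± 0.21). The members that were higher were the elongase ELOVL6 (0.43 ± 0.12) and ACSL1 (0.38 ± 0.11) in the authors' deposited table.

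Glucose genes gave individual large changes but no shared direction. Of 10 listed genes of gluconeogenesis and glycogen metabolism, 7 were lower (Fisher's exact test, adjusted p = 0.757). Besides G6PC, the authors' deposited table gave -0.76 ± 0.19 for the transcription factor KLF15 and -0.50 ± 0.19 for PCK1, the enzyme of the first committed step of gluconeogenesis, with an adjusted p of 0.0453 near the authors' threshold, while FOXO3 was higher (0.75 ± 0.11). In glycolysis and glucose uptake 7 of 9 were lower (Fisher's exact test, adjusted p = 0.481), led in the authors' deposited table by SLC2A2 and by MLXIPL, a glucose-responsive transcription factor (-0.94 ± 0.12). Insulin and IGF signalling genes were divided, 3 higher and 4 lower (Fisher's exact test, adjusted p = 1.00). The extremes in the authors' deposited table were SOCS2, a feedback inhibitor of growth hormone signalling (1.40 ± 0.17, 2.64-fold), and IGFBP1, a secreted IGF binding protein (-1.19 ± 0.12, 2.28-fold lower). FOXO1, IGF2, IGF2BP1 and HMGA2 were also among the genes fixed by name and were not analysed here.

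Extracellular matrix and TGF-beta target genes were the 1 list that rose. Of 15 listed members, out of 48 symbols, 12 were higher, with a median of 0.55 (Fisher's exact test, adjusted p = 0.0432). These included the actin-binding protein TAGLN (0.84 ± 0.12), the collagen COL4A5 (0.73 ± 0.11), SPARC (0.65 ± 0.12), TGFB1 (0.58 ± 0.12) and thrombospondin THBS1 (0.55 ± 0.09) in the authors' deposited table. The 3 that were lower in the authors' deposited table were the receptor TGFBR2, ACTA2 and CTGF (-0.30 ± 0.09). The call was kept under 3 of 9 alternatives and was lost, for example, at an adjusted p threshold of 0.01 (adjusted exact p = 0.208) and without genes that overlap another listed gene, TAGLN among them (0.0608), within a range of 0.0172 to 0.225. Epithelial junction and mesenchymal genes were mixed, 4 higher and 3 lower (Fisher's exact test, adjusted p = 0.856), from the integrin ITGB4 (0.93 ± 0.14) to the tight junction protein CLDN2 (-1.01 ± 0.20) in the authors' deposited table.

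**Figure D3:**
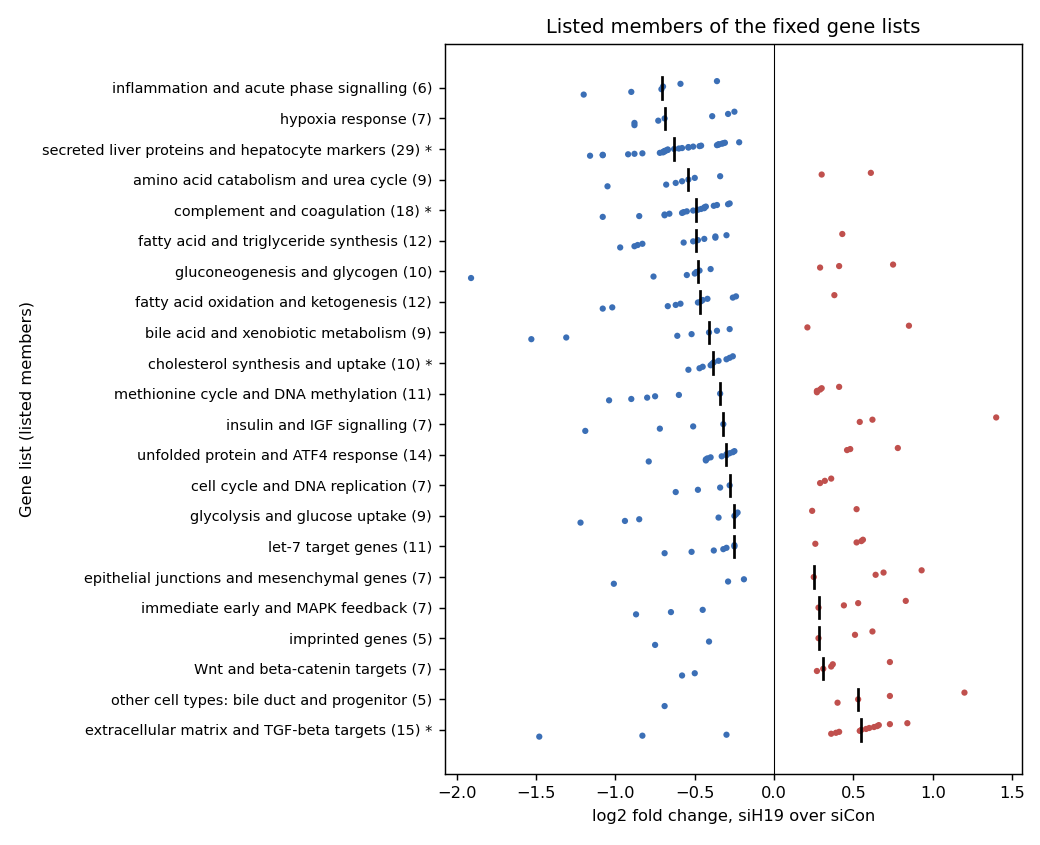
Each point is a listed gene's log2 fold change, siH19 over siCon, in the authors' deposited table (x axis), by fixed gene list (y axis, with the number of listed members), red for higher and blue for lower, and black bars are list medians, with 1 tested list not drawn. Stars mark the 4 of 23 tested lists with an adjusted p under 0.05 by Fisher's exact test of direction, the hepatocyte (median -0.63), complement (-0.50), cholesterol (-0.39) and extracellular matrix (0.55) lists.

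Bile acid, amino acid and methionine metabolism each held strongly lowered genes. For bile acid and xenobiotic genes 7 of 9 were lower, led by SULT2A1 and NR1H4, and in the authors' deposited table BAAT, which conjugates bile acids, was higher (0.85 ± 0.18). For amino acid catabolism and the urea cycle 7 of 9 were lower, among them histidase, HAL (-1.05 ± 0.21), and tyrosine aminotransferase, TAT (-0.68 ± 0.18), with CPS1 higher (0.61 ± 0.10) in the authors' deposited table. Both lists had an adjusted p of 0.481 by Fisher's exact test. The methionine cycle and DNA methylation list was divided, 5 higher and 6 lower (Fisher's exact test, adjusted p = 1.00). Its lower members in the authors' deposited table included the homocysteine methyltransferases BHMT2 (-1.04 ± 0.11) and BHMT (-0.90 ± 0.20), similar paralogs that each overlap another listed gene in the annotation, so that reads could be shared, and the liver enzyme MAT1A (-0.80 ± 0.10). The higher members in the authors' deposited table included AHCY, which hydrolyses S-adenosylhomocysteine (0.27 ± 0.09, adjusted p = 0.0235), and DNMT1 and UHRF1, which maintain DNA methylation (0.27 ± 0.09 and 0.41 ± 0.12).

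Genes tied to H19 by earlier knowledge moved in both directions. Of 5 listed imprinted genes 3 were higher (Fisher's exact test, adjusted p = 0.856), from GRB10 (0.62 ± 0.13) to SLC38A4 (-0.75 ± 0.21) in the authors' deposited table. A list of 5 is too small to pass this test in either direction. Of 11 listed targets of the let-7 microRNAs, which H19 can bind, 7 were lower (Fisher's exact test, adjusted p = 0.878). In the authors' deposited table they ran from ONECUT2 (-0.69 ± 0.13) to the helicase DNA2 (0.56 ± 0.13), with LIN28B, an inhibitor of let-7 maturation, at 0.26 ± 0.08 (adjusted p = 0.0155). Within 2 Mb of H19, by gene positions in GENCODE release 29, the authors' deposited table held MRPL23-AS1 (-0.66 ± 0.21), TSPAN4 (-0.41 ± 0.15), BET1L (-0.41 ± 0.11), PKP3 (0.45 ± 0.13), ZNF195 (0.35 ± 0.11) and CARS (0.34 ± 0.10). Of the RNA interference machinery, DICER1 was lower (-0.25 ± 0.08) and TNRC6A higher (0.55 ± 0.10) in the authors' deposited table.

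Stress and inflammatory genes leaned lower without passing the direction test. All 6 listed inflammation genes were lower (Fisher's exact test, adjusted p = 0.104), among them CCL20 (-1.20 ± 0.17), the interleukin-1 receptor antagonist IL1RN (-0.90 ± 0.14) and ICAM1 (-0.71 ± 0.07) in the authors' deposited table. All 7 listed hypoxia response genes were lower (Fisher's exact test, adjusted p = 0.0631), led by LOX (-0.88 ± 0.15) and P4HA1 (-0.88 ± 0.10), which crosslink and hydroxylate collagen, in the authors' deposited table. Their medians, -0.71 and -0.69, did lie beyond those of random sets of listed genes (permutation test, adjusted p = 0.0253 for each). With all members lower, these lists of 6 and 7 already gave the smallest exact p that a fall allows. Neither could therefore pass the direction test by falling, and not passing is no evidence against a shared fall. In the unfolded protein and ATF4 list 11 of 14 were lower (Fisher's exact test, adjusted p = 0.269), including the chaperone HSPA5 (-0.30 ± 0.10) and NUPR1 (-0.79 ± 0.13), with ATF3 higher (0.78 ± 0.15) in the authors' deposited table. The 3 listed interferon genes were SAMD9 (0.85 ± 0.22, at a low mean count of 27.8), USP18 (-0.43 ± 0.15) and IFI35 (-0.42 ± 0.14) in the authors' deposited table, too few for a test.

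Growth control genes and members of other lists were likewise divided. CYFIP2 was higher (0.57 ± 0.10), and the cyclin CCNG1 (-0.99 ± 0.10) and the cyclin kinase inhibitor CDKN1A (-0.40 ± 0.08) were lower in the authors' deposited table. Cell cycle genes were 3 higher and 4 lower (Fisher's exact test, adjusted p = 1.00), with the mitotic kinase AURKA at -0.62 ± 0.07 and TOP2A at -0.48 ± 0.12 in the authors' deposited table. All 3 listed replication-dependent histones were higher, HIST1H1D (0.79 ± 0.21), HIST1H1B (0.43 ± 0.11) and HIST1H3D (0.36 ± 0.12) in the authors' deposited table. Of 7 listed genes in the Wnt and beta-catenin list 5 were higher (Fisher's exact test, adjusted p = 0.481), including beta-catenin itself, CTNNB1 (0.37 ± 0.09), and SOX4, with the inhibitor DKK1 lower (-0.58 ± 0.10) in the authors' deposited table. Immediate early genes were 4 higher and 3 lower (Fisher's exact test, adjusted p = 0.856), with DUSP4 at 0.83 ± 0.21 and EGR1 at -0.87 ± 0.17 in the authors' deposited table. The 3 listed ribosomal protein genes were slightly lower, RPL13A (-0.24), RPL12 (-0.22) and RPS12 (-0.21), and genes commonly used as references also moved in the authors' deposited table, PGK1 (-0.35 ± 0.09), GAPDH (-0.23 ± 0.08) and TUBB (0.35 ± 0.07). Mitochondrial encoded genes had 0 listed members.

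Across the 1998 genes, which are not independent replicates, mean count and log2 fold change had a Spearman correlation of -0.0447 (permutation test, p = 0.0451). This call was lost at an adjusted p threshold of 0.01 (-0.0516, permutation p = 0.0637), at mean levels at or above the median (-0.0478, permutation p = 0.131) and at 2-fold (-0.211, permutation p = 0.0557). It was kept under the other alternatives, such as 1.5-fold (-0.133, permutation p = 0.00148) and a threshold of 0.001 (-0.0746, permutation p = 0.0329). Of the 200 genes with the highest mean counts, where APOB, SERPINA1, ALB and other liver transcripts lie, 70.0% were lower, against 51.0% of the 200 with the lowest. None of 23 chromosomes passed correction (Fisher's exact test, smallest adjusted p = 0.104), and 4 had an unadjusted exact p under 0.05, while chromosome 4 passed without genes that overlap another listed gene (exact adjusted p = 0.0436). Of these, chromosomes 3 and 4 had more lower genes (65.4% and 70.2%) and chromosomes 15 and 19 fewer (39.7% and 42.2%).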

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

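Removal of genes that overlap another listed gene, of genes with either 3' UTR sequence or an unsearched 3' UTR and of members shared between lists was chosen after the data were seen. So were 0.001, 2-fold and the removal of unmatched and pseudogene rows for the list, abundance and chromosome results, and the minimum level for the latter pair. The number of genes fell by construction, to 1294 and 814 at adjusted p thresholds of 0.01 and 0.001, to 563 and 83 at 1.5-fold and 2-fold, and to 999 at a mean count at or above the median. The excess of lower genes kept its direction under all 8 alternatives and was lost as a call only at 2-fold (57.8%, exact binomial test, p = 0.187), where fewer genes are tested. The correlation with abundance kept its sign and was lost at 0.01 (-0.0516, permutation p = 0.0637), at a mean count at or above the median (-0.0478, permutation p = 0.131) and at 2-fold (-0.211, permutation p = 0.0557). Without overlapping genes 1 chromosome passed, chromosome 4, with 57 genes lower and 23 higher (exact adjusted p = 0.0436), and the cause was not tested. The number of lists that passed fell from 4 to 2 at each stricter adjusted p threshold (hepatocyte and complement), to 1 at a mean count at or above the median and at 1.5-fold (hepatocyte), and to 0 at 2-fold, where 3 hepatocyte genes were left and were not tested. The hepatocyte call held under all 9 alternatives that could test it (exact or permutation adjusted p from 3.47e-07 to 6.39e-04). Among the 1469 genes searched and found without either 3' UTR sequence (unsearched genes also removed) 4 lists passed, fatty acid oxidation in place of extracellular matrix (exact adjusted p = 0.0384 and 0.0607). No result reversed. No paired analysis was possible because the authors combined the replicates into 1 value per group, and for the same reason the other normalization, low count filter, pseudocount, leave-one-out fits and other splits of the libraries were not run. Depth is unknown, so what it limits could not be judged beyond the low counts.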

Other observations

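The tests of gene families, the search for 3' UTR sequences, the microRNA site tests and all weighing of explanations were chosen after the gene table had been seen, and the tests of dilution and of base composition also after related results were known. Among 32 families of genes that share a symbol stem, solute carriers fell and collagens and zinc finger genes rose. Of 50 listed genes named SLC, nearly all of them membrane transporters, 42 were lower (Fisher's exact test, adjusted p = 6.14e-04). In the authors' deposited table the falls beyond SLC2A2 included the organic cation transporter SLC22A3 (-1.06 ± 0.13), the glutamate transporter SLC1A2 (-0.88 ± 0.10), the citrate transporter SLC13A5 (-0.64 ± 0.09), the zinc and manganese transporter SLC39A14 (-0.59 ± 0.07), and SLC51A and SLC51B, the subunits of a bile acid exporter (-0.58 each, at low mean counts of 17.2 and 58.4). All 9 listed collagen genes were higher (exact adjusted p = 0.00742), led in the authors' deposited table by COL4A6, a basement membrane chain (0.96 ± 0.14), COL7A1 (0.87 ± 0.20), COL16A1 (0.74 ± 0.13) and the basement membrane chain COL4A5 (0.73 ± 0.11). COL18A1, COL6A1 and COL4A5 are also members of the fixed extracellular matrix list, so the family count is not independent of it.

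Of 40 listed genes named ZNF, 29 were higher (Fisher's exact test, adjusted p = 0.00742), and of 17 named LOC, a stem for uncharacterized loci, 15 were lower (exact adjusted p = 0.0473). The semaphorins, guidance molecules, did not pass, with 6 of 7 higher (exact adjusted p = 0.266), among them SEMA3A (1.05 ± 0.16), SEMA4F (1.04 ± 0.15) and SEMA3G (1.02 ± 0.12) in the authors' deposited table. Among the 1469 genes searched and found without either of the 3' UTR sequences described next, which leaves out unsearched genes too, SLC genes were 4 higher and 31 lower, ZNF genes 20 and 5, and COL genes 7 and 0, and each still passed (exact adjusted p = 2.49e-04, 0.00559 and 0.0198).

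The first pattern is the tie between fold change and short 3' UTR sequences: of 14263, CATCAAA was the one most tied to lower values (z = -8.63) and GCAGTAC the one most tied to higher values (z = 10.4), each beyond all 1000 shuffles (permutation p = 0.000999, the smallest they can give). Sequences that overlap these also passed the shuffled limits: ACATCAA (z = -7.17) on the lower side, and CAGTACA (5.97) and CAGTACT (4.61) on the higher side. Genes that held only such overlapping sequences were counted as without either sequence. Longer sites had a more uneven split, but more copies did not for CATCAAA: 83.9% of the 124 genes with ACATCAAA were lower, against 67.4% of 178 with the 7-base site only and 66.1% of 56 with 2 or more copies, and 88.7% of the 71 genes with GCAGTACA were higher, against 80.0% of 90 with the 7-base site only and 10 of 10 with 2 or more copies. These groups were not tested against each other, and genes with 2 or more copies also stand in the other groups. The GC content of the 3' UTR was in the model behind each z, which argues against GC content as the cause. The larger z of both reverse complements was 1.55, but these exchange A with T, so richness in 1 base such as A is not excluded. The tables argue against an effect of the sequence anywhere in the transcript. Copies of CATCAAA outside the 3' UTR went with a difference of -0.0556 (95% interval -0.123 to 0.0119), against -0.32 inside it. CATCAAA occurs once (1 copy) in 10 of 12 annotated H19 transcripts and GCAGTAC in 0. Of the tested sequences 15.6% occur in any H19 transcript, so this presence and absence are weak evidence. A candidate explanation, as a hypothesis, is seed pairing of the H19 siRNA guide strand with falling genes such as TGFBR2 and SLC2A2. The control siRNA could likewise pair with genes such as XPR1 and YWHAH, which would be lowered in siCon. The siRNA sequences were not given in the sources used here, an endogenous microRNA with either seed stays open, and so does how many changes follow from H19 itself.

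The second pattern is the uniform direction of the hepatocyte genes. Listed genes matched to them on mean count were lower in 63.5% of cases (upper 95% limit of matched draws 79.3%, permutation p = 1e-05, the smallest possible), against 100% observed, and with transcript length, GC content and mean count in the model the list still lay -0.45 below other listed genes (95% interval -0.56 to -0.33). Dilution by other cells alone would lower all members by 1 factor. Their fold changes instead spread beyond the SEs by 0.205 (0.145 to 0.249) on the log2 scale, and all libraries came from HepG2 cells. These values argue against dilution as the sole cause for the 29 members, so far as the SEs cover the spread between cultures. The libraries may be technical replicates, and the low mean count of ITIH4 (21.4) leaves its SE in doubt. The tables also argue against direct pairing at CATCAAA or GCAGTAC in the 3' UTR, since 0 of 29 members hold either sequence. Among the 1469 searched genes without them the difference was -0.49 (-0.61 to -0.37), a comparison that removed no member of the list. The overlapping sequences ACATCAA and CAGTACA, which also passed the shuffled limits, were not looked up in the members, so pairing there stays open. A shared biological change of hepatocyte identity may underlie the pattern, which these data do not settle, and dilution as a part of it is not excluded. A role for HNF4A or CEBPA, which are members of the list, was not tested, nor was whether the fall follows from H19 or, at 1 or more steps, from a gene whose 3' UTR holds CATCAAA, such as TGFBR2.

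The third pattern concerns microRNAs linked to H19, which binds let-7 and is the precursor of miR-675. If lost H19 freed let-7, genes with its 3' UTR site would be lower, but 225 such genes differed by -0.0351 (95% interval -0.116 to 0.0460), which leaves both no effect and a fall of 0.1 open, so that these cannot be told apart. Genes with a site for miR-675-5p (80) or miR-675-3p (144) would be higher if these microRNAs were lost, and they differed by -0.0551 (-0.187 to 0.0772) and -0.0247 (-0.134 to 0.0844), which leaves out a mean rise of 0.1. These tests cover listed genes only, and the levels of the microRNAs were not analysed here.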
